A study of Mus musculus with 6 samples.

How the data were processed

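RNA was sequenced from haematopoietic stem and progenitor cells (lineage-negative, Sca1-positive, cKit-positive) sorted from femur and tibia marrow of adult C57BL/6 mice, in 3 libraries labelled wild type (WT) and 3 labelled Drd2/Drd3 double knockout (KO). Per the labels' protocols, cDNA was made with the SMART-Seq v4 Ultra Low Input kit and libraries with Nextera XT, a combination that does not mark strand. The deposited table holds FPKM values, reads per kilobase of gene and per sequencing depth as the authors scaled them, for 38926 gene symbols and 6 libraries. The submitters' processing notes name bcl2fastq 2.19.1.403, TopHat2 2.1.1, HTSeq 0.6.1, DESeq2 1.18.1 and build mm10 without their roles or order, and the annotation used is not given.

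Within a gene, the FPKM values of different libraries stood to each other as whole numbers once each library was multiplied by its divisor. This held for all 17183 genes above 0 in 2 or more libraries (relative tolerance 1e-12). The 2190 genes above 0 in 1 library have no such ratio. Where the exon length in GENCODE M21 was a whole multiple of the implied gene length, reads were scaled up to match it. In other genes they were taken as the smallest number that gave a whole gene length (tolerance 1e-08 bases). The implied length then equalled the exon length in GENCODE M21 for 10238 genes (52.8%). The scaling, and a divisor set on these same lengths, help to make this share. Reads scaled to the annotation rest on its lengths. In the other genes a common factor may be missing, so their recovered reads are lower bounds. The divisors were proportional to median-of-ratios size factors. Recovered reads per library were 5245416 to 7148421, so 1 read in a transcript of 2000 bases stood for 0.0693 to 0.0921 FPKM. The 10 highest genes held 3.66 to 4.22% of the reads of a library. Positions in build GRCm38 were found for 37321 symbols (95.9%).

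The 3 libraries labelled KO were compared with the 3 labelled WT in limma 3.58.1 (R 4.3.3), with lmFit and eBayes with a mean-variance trend on log2(FPKM + 1), for 11371 genes with a mean of at least 1 FPKM over all 6 libraries. Two-sided p-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. Fold changes on this scale understate those of low genes. For a gene at 0 in every library of a group, a bound on the fold was computed with 3 reads in each of these libraries. Bounds and intervals from reads cover counting error only. Preparation and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

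Before the data were examined, 30 gene lists were fixed: stem cell, multipotent progenitor, lymphoid, granulocyte and monocyte, and megakaryocyte and erythroid priming; S phase, G2 and M phase, and quiescence; Src-family and Kit-MAPK signalling, MAPK output, immediate early, cAMP-PKA, dopamine and noradrenaline, p53, interferon, NF-kB, heat shock, oxidative phosphorylation, glycolysis, ribosomal and niche genes; markers of mast, T and NK, B and plasma, neutrophil, macrophage and dendritic, erythroid, and endothelial and stromal cells; neighbours of Drd2 and Drd3; and sex-linked genes, given as values. The other 29 were tested with fry and with limma's camera, which compares a list with all other genes. Camera was run with a preset correlation of 0.01 and again with an estimated one. Members were matched by exact symbol, so those listed under an older symbol were not tested. Among these was Jchain (listed as Igj) of the lymphoid list and the B and plasma cell list. After the data were seen, 4 lists were added (haem synthesis, imprinted genes, mast cell proteases and amino acid response), and plasma cell genes were listed to describe libraries. Genes within 10 Mb of Drd2 or Drd3 were compared with all others by a one-sided Fisher's exact test.

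Genes were named by a rule also fixed before: the dopamine receptors; the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, predicted models and pseudogenes left out; up to 4 called members of a list by smallest p; and Lck and Kit. Of lists that camera did not call, most called members are given as counts alone. A few genes that the rule names are not reported here. Exceptions are marked as chosen after their values were seen.

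Reads were simulated at the depth of this comparison, with 200 changed genes and 43 S phase genes shifted by -0.5 on the log2 scale. The spread of the simulated reads was smoothed over genes and shared by both groups. On these reads (11244 genes tested) the test called 11.1, 57.6 and 90.6% of genes changed by 0.5, 1 and 2 on the log2 scale. Of its calls, 11.1% were unchanged genes. Voom on the same simulated reads called 28.6, 71.2 and 92.2%, with 5.13% unchanged genes among its calls. In the data the spread was not shared: Pearson's r was 0.963 to 0.970 between KO libraries and 0.983 to 0.985 between WT libraries. The simulated shares therefore need not hold for this comparison. Camera with the preset correlation called 0 of 28 lists without a change, but each gene was drawn independently. In the data the 8 called lists had estimated correlations of 0.0510 to 0.601. The simulation therefore cannot show how often camera calls an unchanged list whose genes vary together.

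Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 5 FPKM, scaling to a common sum, centring on the median, quantile normalization, no trend, robust eBayes, array weights, limma's voom on recovered reads, the replicate number as a block, an adjusted p under 0.1, a log2 fold change of at least 1, and each library left out in turn. A term for Y-linked transcripts and the comparison without the 2 KO libraries lacking them were added after the data were seen. In both, the difference between the groups rests on KO replicate 2 alone, so they are not separate checks. No library was left out of the comparison itself.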

Results

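Gene expression was measured by RNA sequencing in haematopoietic stem and progenitor cells of adult C57BL/6 mice. The cells were sorted from femur and tibia marrow as lineage-negative, Sca1-positive and cKit-positive (LSK), a gate that holds stem cells and multipotent progenitors. There were 6 libraries, 3 labelled wild type (WT) and 3 labelled Drd2/Drd3 double knockout (KO). The deposited table gave FPKM for 38926 gene symbols, of which 19373 were above 0 in at least 1 library. Whole reads recovered from the FPKM values came to 6201381, 5903182 and 6196234 in WT replicates 1 to 3 and to 7148421, 6814295 and 5245416 in KO replicates 1 to 3. The number of genes above 0 ran from 15632 to 16220 per library. Across the tested genes, Pearson's r was 0.983 to 0.985 between WT libraries, 0.963 to 0.970 between KO libraries and 0.949 to 0.956 between the groups. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples.

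The targeted genes encode the D2-like dopamine receptors Drd2 and Drd3. Drd2 (chromosome 9, 49340627 to 49408177, build GRCm38, which is mm10) was listed at 0 FPKM in all 6 libraries. Drd3 (chromosome 16, 43754026 to 43822932) was listed at 0 in the 3 libraries labelled WT, and at 1.62, 3.08 and 3.04 FPKM in the libraries labelled KO replicates 1, 2 and 3, which is 72 reads in all. The mean in the libraries labelled KO was 2.58 ± 0.833 FPKM (SD, n = 3), at least 7.65-fold higher than in those labelled WT (limma adjusted p = 0.00344), taking 3 reads per WT library as the floor for a value of 0. Drd3 therefore went against the labels, and Drd2 gave no check of them. Which exons are altered is not given in the sources used here, and the table gives 1 value per gene. Every direction that follows is the direction between the libraries labelled KO and those labelled WT. Among the other dopamine receptors, Drd1 (listed as Drd1a) and Drd5 were at 0 in every library. Drd4 was at 0 except for 0.128 FPKM (1 read) in the library labelled WT replicate 2 and 0.208 FPKM (2 reads) in that labelled KO replicate 1.

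The libraries also differed in sex-linked transcripts. The Y-linked gene Ddx3y was at 13.9, 13.3 and 12.5 FPKM in the libraries labelled WT and at 15.1 FPKM in that labelled KO replicate 2, and was at 0 in those labelled KO replicates 1 and 3. Xist, the transcript of the inactive X chromosome, was at 1.96 and 2.01 FPKM in these same 2 KO libraries and at 0 in the other 4. The groups were thus not balanced for sex, and the library labelled KO replicate 2 did not come from the same animals as those labelled KO replicates 1 and 3. The same 2 KO libraries stood apart in the immunoglobulin kappa light chain. Igkc, its constant region, was at 3182 and 1173 FPKM in those labelled KO replicates 1 and 3, against 4.93 FPKM in that labelled KO replicate 2 and at most 2.48 FPKM in those labelled WT.

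**Figure D1:**
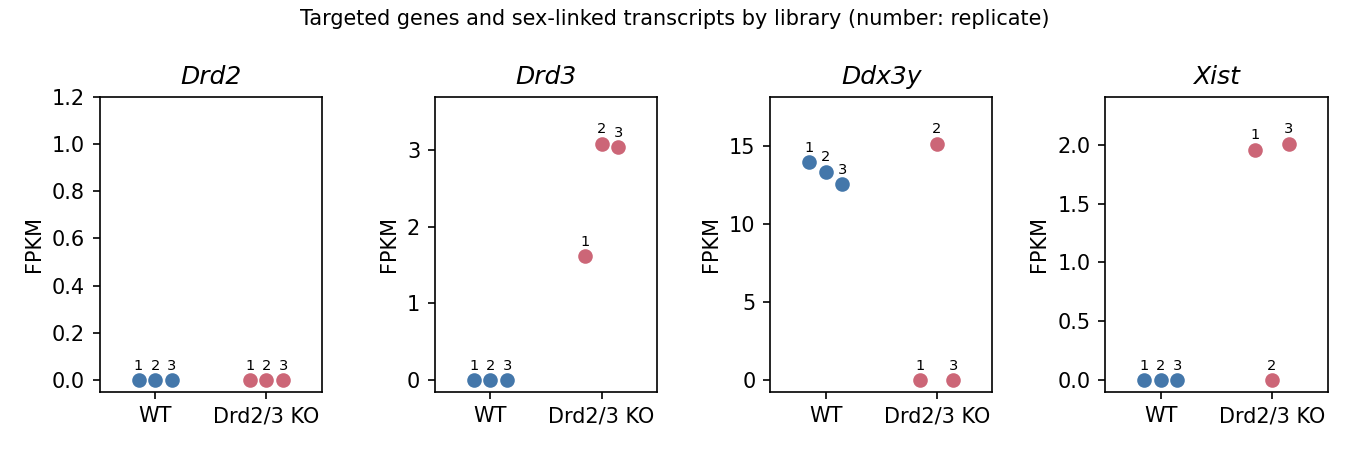
FPKM of Drd2, Drd3, Ddx3y and Xist in each library, with the replicate number beside each point and the groups as labelled. Drd2 was at 0 throughout, Drd3 was above 0 in the 3 libraries labelled KO, and Ddx3y and Xist part the libraries labelled KO replicates 1 and 3 from the other 4.

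The comparison of KO with WT asked which genes of LSK cells differ when both receptors are targeted. In the libraries labelled KO, 19 of 31 genes that mark haematopoietic stem cells and 12 of 27 of megakaryocyte and erythroid priming rose. There, 8 of 16 multipotent progenitor, 7 of 20 lymphoid priming, 32 of 52 G2 and M phase, 15 of 43 S phase and 9 of 25 inflammatory genes fell. As lists, these passed limma's camera with a preset correlation (adjusted p of at most 0.0161) and none did with an estimated correlation (adjusted p = 0.329, and 0.379 for lymphoid priming). The erythroid transcription factor Klf1 rose from 19.6 ± 4.07 to 87.6 ± 41.4 FPKM (SD, n = 3 per group throughout). The cytokine receptor Flt3, a marker of multipotent progenitors, fell from 82.7 ± 9.76 to 34.9 ± 3.45 FPKM, and Dntt, the terminal transferase of lymphoid precursors, fell from 327 ± 22.2 to 95.3 ± 26.2 FPKM. The neutrophil chemokine Cxcl2 fell from 32.9 ± 3.95 to 4.40 ± 0.728 FPKM.

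Of 11371 genes with a mean of at least 1 FPKM, 1240 (10.9%) differed in limma's test on log2(FPKM + 1) at a Benjamini-Hochberg adjusted p under 0.05, 623 higher and 617 lower in the libraries labelled KO. Of these, 326 differed by at least 1 on the log2 scale, 196 higher and 130 lower. The median log2 fold change of all tested genes was -0.002. The values of the groups did not overlap in 3727 genes (32.8%, where chance gives 10%), and 97 of the 1240 were pseudogenes or predicted models. The count fell to 531, 370 and 509 without WT replicates 1, 2 and 3 and to 824 without KO replicate 1, and to 588 with no filter on low values (19373 genes tested). It was 373 with a term for Y-linked transcripts and 514 without the 2 KO libraries that lack them, which leaves 1 KO library. Both were chosen after the data were seen, and in both the difference between the groups rests on KO replicate 2 alone.

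With pseudogenes and predicted models left out, the largest rises among genes whose groups did not overlap began with Ifi44l, an interferon-induced gene listed at 0 in the 3 libraries labelled WT and at 26.1 ± 7.67 FPKM in those labelled KO. Its log2 fold change was 4.72 ± 0.23 SE on the log2(FPKM + 1) scale (limma adjusted p = 1.82e-05), and it was at least 25.8-fold higher by the 3-read floor. The antisense gene BC018473 was at least 168-fold, the guanylate-binding protein gene Gbp2b at least 55.8-fold and the mast cell tryptase gene Tpsb2 at least 17.9-fold higher, each listed at 0 in every library labelled WT. Fn3krp, a protein deglycating kinase, rose from 0.106 ± 0.0970 to 16.2 ± 3.14 FPKM and the mast cell chymase Cma1 from 0.149 ± 0.258 to 9.32 ± 4.80 FPKM. The RNA-binding protein gene Rbm45 rose by 3.85 ± 0.34, Rnd3 by 3.60 ± 0.23 and the serine/threonine kinase gene Pim1 by 3.01 ± 0.30 on the log2 scale (SE). Pim1 went from 20.5 ± 2.0 to 187 ± 82 FPKM. The library kit does not mark strand, so reads of BC018473 cannot be told from those of a gene on the other strand, and reads of Gbp2b, Tpsb2 and Rnaset2b may be shared with near-identical relatives.

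The largest falls were led by Mir5136, a microRNA gene (-2.82 ± 0.39 SE, limma adjusted p = 0.00355) with only 5, 3 and 5 recovered reads in the libraries labelled WT and 0, 1 and 0 in those labelled KO, and by Cxcl2 (-2.65 ± 0.15, adjusted p = 3.53e-05). Rnaset2b fell from 10.1 ± 1.29 to 1.29 ± 0.306 FPKM, Khsrp, an RNA decay factor, from 22.0 ± 3.31 to 4.77 ± 1.11 FPKM, and Btla, an inhibitory lymphocyte receptor, from 4.99 ± 1.62 to 0.302 ± 0.0428 FPKM. Inflammatory genes were among these falls: Il1b fell by 1.87, Nfkbiz by 1.91 and the acute-phase protein gene Hp by 1.93 on the log2 scale. Hp missed the threshold with the term for Y-linked transcripts (adjusted p = 0.0946; 0.00369 to 0.0946 over its alternatives). Cox6a2 fell by 2.1 (adjusted p = 0.00993) but missed the threshold without WT replicate 2 (adjusted p = 0.0556; 0.00123 to 0.120 over its alternatives). Ighv1-62-1, with 3, 1 and 3 recovered reads against 0, 1 and 0, fell by 1.83 (adjusted p = 0.0280). It missed the threshold without WT replicates 1 and 3 and KO replicates 1 and 3 (adjusted p = 0.106, 0.101, 0.0907 and 0.0646; 0.0123 to 0.307 over its alternatives).

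**Figure D2:**
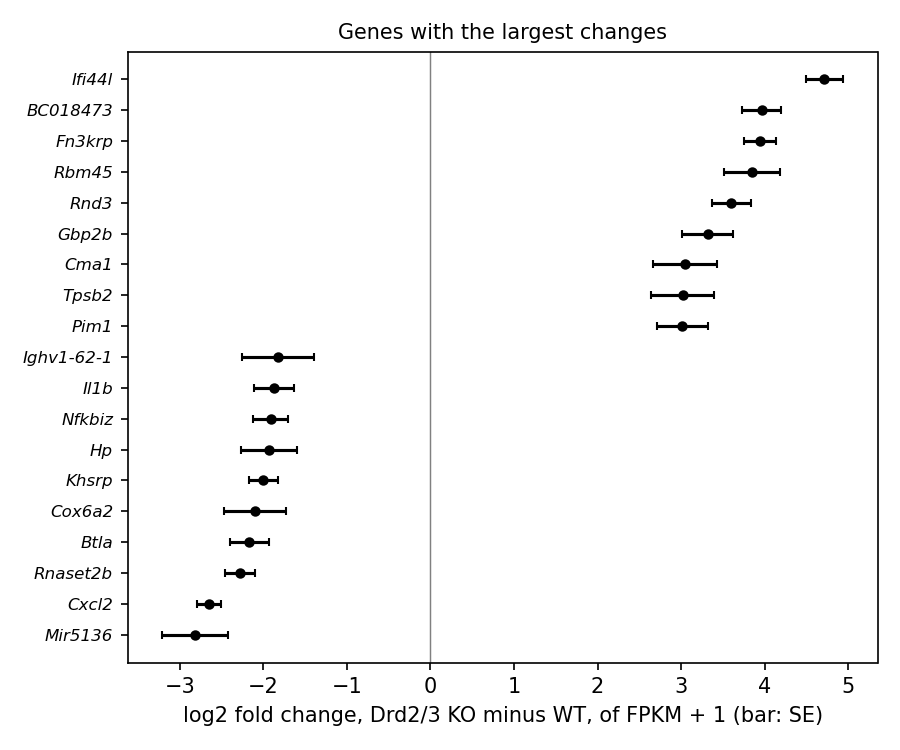
Log2 fold change on the log2(FPKM + 1) scale, libraries labelled KO minus those labelled WT, of genes with the largest rises and falls among those past the test without overlap, pseudogenes and predicted models left out; bars are standard errors. The rises run up to 4.72 (Ifi44l) and the falls down to -2.82 (Mir5136).

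Of 29 gene lists, limma's camera with a preset correlation of 0.01 called 8 at an adjusted p under 0.05, 3 higher and 5 lower in the libraries labelled KO. With an estimated correlation limma's camera called 0 of the 29 (3 at an unadjusted p under 0.05), and the adjusted p was 0.329 for 6 of the 8, 0.379 for lymphoid priming and 0.595 for the erythroid list. The fry test, which asks whether the genes of a list move on balance one way and does not compare the list with other genes, called 7, all but the erythroid list. The term for Y-linked transcripts leaves KO replicate 2 alone to set the difference between the groups. In this library the medians of the 8 lists lay on the same side of the WT mean as in the fit of all 6 libraries.

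Of 31 tested stem cell genes, 19 rose and none fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 0.83 (camera adjusted p = 4.69e-14, fry adjusted p = 0.0108; adjusted p = 0.329 with an estimated correlation). Sult1a1, a sulfotransferase, rose from 4.68 ± 0.951 to 21.0 ± 1.2 FPKM, Pdzk1ip1 from 45.6 ± 2.87 to 102 ± 6.62 FPKM, and the interferon-induced membrane protein gene Ifitm1 from 343 ± 4.55 to 706 ± 85.9 FPKM. The stem cell regulators Hlf, Meis1, Mecom and Hoxa9, chosen after their values were seen, did not pass, with log2 fold changes of -0.09, 0.17, 0.41 and 0.09. With the term for Y-linked transcripts 10 members rose, and 11 did without the 2 KO libraries lacking them.

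Of 16 tested multipotent progenitor genes, 8 fell and none rose (9 and 0 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 6.33e-07, fry adjusted p = 0.0108; adjusted p = 0.329 with an estimated correlation). Besides Flt3, the surface protein gene Cd52 fell from 99.4 ± 8.36 to 41.5 ± 9.45 FPKM, the chromatin organiser Satb1 from 18.9 ± 2.07 to 6.38 ± 1.49 FPKM and Cd33 from 5.38 ± 0.306 to 1.67 ± 0.395 FPKM. With the term for Y-linked transcripts 5 members fell. Of 20 lymphoid priming genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.0161, fry adjusted p = 0.0188; adjusted p = 0.379 with an estimated correlation). Dntt and the transcription factor gene Mef2c fell, by 1.81 and 0.67 on the log2 scale, while the lymphotoxin gene Ltb and the GTPase gene Gimap6 rose by 1.02 and 0.80. Without WT replicate 1 and without WT replicate 2, 4 lymphoid members fell. The lymphoid call was lost without KO replicate 3 (adjusted p = 0.0636; 0.0102 to 0.379 over its alternatives), without the 2 KO libraries that lack Y-linked transcripts (adjusted p = 0.0608) and with a mean of at least 5 FPKM (adjusted p = 0.242).

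Of 27 tested megakaryocyte and erythroid priming genes, 12 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 2.54e-07, fry adjusted p = 0.0255; adjusted p = 0.329 with an estimated correlation). The blood group gene Rhd rose from 9.93 ± 2.34 to 51.3 ± 18.7 FPKM, and the erythropoietin receptor gene Epor from 4.20 ± 1.15 to 18.8 ± 7.88 FPKM. Plek, which encodes the platelet protein pleckstrin, fell from 71.4 ± 11.8 to 33.8 ± 5.98 FPKM. Without WT replicates 1, 2 and 3, 7, 7 and 6 members rose. Of 15 erythroid cell genes, 5 rose and none fell (12 and 0 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 1.78e-05, fry adjusted p = 0.0941; adjusted p = 0.595 with an estimated correlation). Rhag rose by 2.34 ± 0.20 (SE) and Fech, the last enzyme of haem synthesis, by 0.77 ± 0.13 on the log2 scale. Without WT replicates 2 and 3, 2 and 3 erythroid members rose. The carbonic anhydrase genes Car2 and Car1 rose by 0.68 and 1.5 in the fit of all 6 libraries. Car2 missed the threshold without WT replicate 2 (adjusted p = 0.0672; 0.00140 to 0.0672 over its alternatives), and Car1 without WT replicates 1, 2 and 3 (adjusted p = 0.138, 0.134 and 0.0608; 0.00299 to 0.151 over its alternatives).

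Of 52 G2 and M phase genes, 32 fell and none rose (42 and 0 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 8.13e-18, fry adjusted p = 0.0132; adjusted p = 0.329 with an estimated correlation). Topoisomerase Top2a fell from 39.1 ± 1.76 to 18.6 ± 2.53 FPKM, the condensin gene Ncapd2 from 43.3 ± 5.29 to 20.1 ± 3.58 FPKM. The mitotic kinesin Kif11 fell from 26.0 ± 2.33 to 13.0 ± 2.11 FPKM, and Cdca2 fell by 0.83 on the log2 scale. Of 43 S phase genes, 15 fell and none rose (30 and 0 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 1.84e-11, fry adjusted p = 0.0188; adjusted p = 0.329 with an estimated correlation). Uhrf1, which maintains DNA methylation at replication, fell from 58.0 ± 3.83 to 26.1 ± 4.67 FPKM, and the polymerase gene Pola1 from 11.3 ± 1.28 to 5.11 ± 1.06 FPKM. The members of the G2 and M phase list that fell were 18, 8 and 10 without WT replicates 1, 2 and 3, and 18 without KO replicate 1; those of the S phase list were 9, 2 and 6, and 7. With the term for Y-linked transcripts 5 and 2 members fell, and 7 and 3 without the 2 KO libraries lacking them. The helicase gene Mcm7 fell by 0.54 and Hells by 0.74 on the log2 scale. Without WT replicate 2 Mcm7 and Hells missed the threshold, and Pola1 did with the term for Y-linked transcripts (adjusted p = 0.0509, 0.0522 and 0.0940; 0.00240 to 0.0920, 0.00183 to 0.0929 and 0.000995 to 0.0940 over the alternatives of each).

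Of 25 tested genes of NF-kB signalling and inflammation, 9 fell and none rose (11 and 0 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 4.85e-07, fry adjusted p = 0.0132; adjusted p = 0.329 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, fell from 117 ± 11.2 to 35.2 ± 3.51 FPKM, and the interleukin 1 receptor gene Il1r1 from 13.2 ± 1.60 to 3.94 ± 0.543 FPKM. Nfkbiz fell from 104 ± 17.8 to 27.5 ± 9.15 FPKM and the cytokine gene Il1b from 120 ± 33.3 to 32.1 ± 9.36 FPKM.

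**Figure D3:**
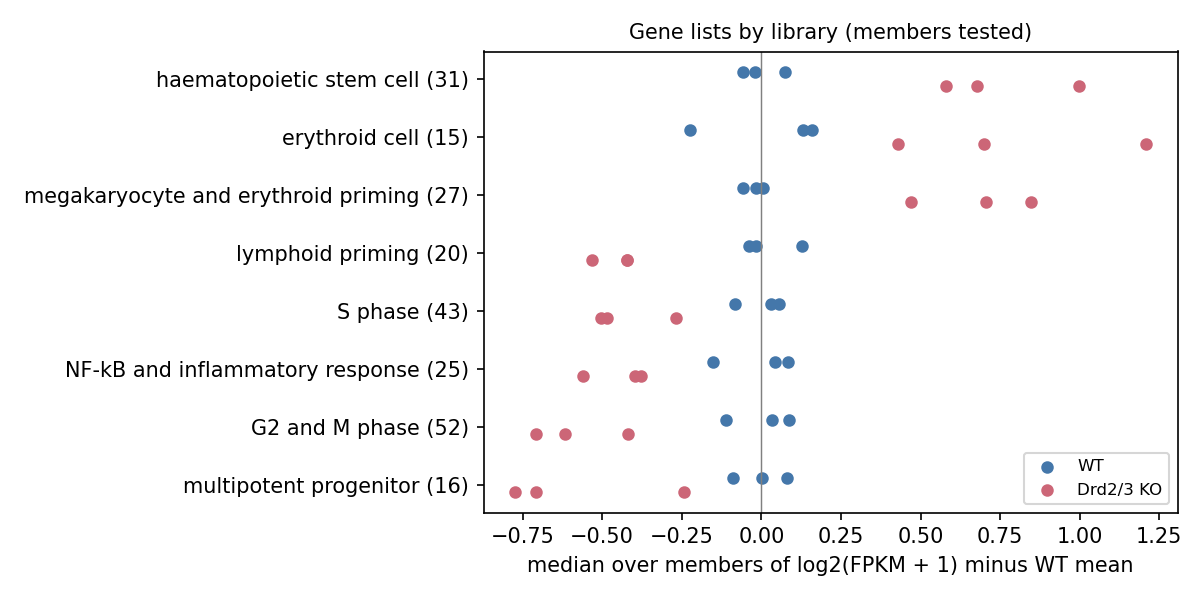
Median over the tested members of each called list of log2(FPKM + 1) minus the WT mean of the gene, for each of the 6 libraries as labelled. The stem cell list lies at 0.58, 0.68 and 1.0 in the libraries labelled KO replicates 1, 2 and 3, and at 0.07, -0.02 and -0.06 in those labelled WT.

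The tyrosine kinase Lck (chromosome 4, 129548344 to 129573641), of the Src family that acts on growth factor receptor signalling, fell from 32.9 ± 1.03 to 14.8 ± 2.45 FPKM (log2 fold change -1.11 ± 0.13 SE, limma adjusted p = 0.00174). The stem cell factor receptor Kit was at 121 ± 25.1 and 101 ± 25.2 FPKM and did not pass (-0.27 ± 0.19, adjusted p = 0.387). In the list of Src-family kinases and Kit-MAPK signalling, 2 of 29 fell and 1 rose (2 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.227). Of its other members past the test, the ubiquitin ligase gene Cbl fell by 1.25 and the MAP kinase kinase gene Map2k1 rose by 0.45. Cbl missed the threshold without WT replicates 1 and 3 and KO replicates 1 and 2 (adjusted p = 0.0533, 0.050, 0.0719 and 0.0534; 0.00871 to 0.162 over its alternatives). Map2k1 missed it without WT replicates 1, 2 and 3 and KO replicate 2 (adjusted p = 0.0618, 0.116, 0.0782 and 0.0522; 0.0178 to 0.136 over its alternatives).

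None of the other 20 lists was called by camera or fry in the comparison of all 6 libraries. By camera, the neutrophil list was called lower without KO replicate 1 (adjusted p = 0.000253, 5 members fell), with the term for Y-linked transcripts (0.000435) and without the 2 KO libraries lacking them (0.000143), in a range of 0.000143 to 0.709 over its alternatives. The interferon list was called higher without KO replicate 2 (adjusted p = 1.44e-05, 6 members rose; 1.44e-05 to 0.713 over its alternatives). Mast cell and basophil genes were called higher without WT replicate 2, without KO replicate 2 and with no filter (adjusted p = 0.0136, 0.0140 and 0.0272; 0.0136 to 0.801 over the alternatives). Ribosomal genes were called lower without WT replicate 1 and without KO replicate 2 (adjusted p = 0.0199 and 0.0140; 0.0140 to 0.907 over the alternatives), with 0 members past the test of single genes in either. Counts here are those that rose and fell of the members tested, each followed by the counts adjusted over the list alone. They were 1 and 1 of 7 (2 and 1) for the dopamine and noradrenaline system, 0 and 1 of 12 (0 and 3) for MAPK output, 4 and 5 of 27 (5 and 6) for immediate early genes. They were 4 and 1 of 26 (4 and 3) for cAMP-PKA signalling, and 5 and 4 of 27 (5 and 5) for granulocyte and monocyte priming. For quiescence and CDK inhibitors they were 4 and 3 of 20 (7 and 5), for p53 targets and apoptosis 2 and 3 of 24 (3 and 4). For the type I interferon response they were 2 and 0 of 30 (2 and 0), and for heat shock and the unfolded protein response 2 and 1 of 22 (2 and 1). Oxidative phosphorylation had 0 and 1 of 40 (0 and 1), glycolysis 2 and 0 of 22 (2 and 0), ribosomal proteins 0 and 0 of 45 (0 and 0) and niche adhesion and homing 4 and 4 of 20 (4 and 5). Among lists of other cell types, mast cells and basophils had 4 and 1 of 13 (6 and 2), T and NK cells 1 and 1 of 8 (1 and 1), and B and plasma cells 1 and 1 of 11 (2 and 1). Neutrophils had 0 and 0 of 14 (0 and 0), macrophages and dendritic cells 0 and 2 of 10 (2 and 2), and endothelial and stromal cells 3 and 2 of 14 (4 and 2). The list of neighbours of Drd2 and Drd3 had 3 and 1 of 29 (3 and 1). Alternatives were run for up to 4 called members of each list by smallest p. Of those not named above, the members past the test in every alternative are given here, a choice made after their values were seen. The immediate early gene Ier3 fell from 238 ± 1.86 to 117 ± 2.04 FPKM and the Kruppel-like factor gene Klf4 rose from 24.9 ± 2.25 to 52.4 ± 10.2 FPKM. The cell cycle inhibitor gene Cdkn1c rose from 13.6 ± 2.48 to 34.3 ± 6.04 FPKM. The sphingosine 1-phosphate receptor gene S1pr1 rose from 25.1 ± 2.40 to 58.3 ± 13.4 FPKM, while the integrin gene Itgal fell from 15.7 ± 1.64 to 7.03 ± 0.687 FPKM. The lectin receptor gene Clec12a and the cystatin gene Cst7 fell by 1.2 and 1.13 on the log2 scale. The protein kinase A subunit gene Prkar2b rose by 0.62, the glutathione transferase gene Gstm1 by 0.68, Asns by 1.43, Trib3 by 1.54 and the endothelial lipoprotein-binding gene Gpihbp1 by 2.05. Beside the Igkc values above, the light chain gene Iglc2 rose by 1.70 in the B and plasma cell list. Iglc2 missed the threshold without WT replicates 1, 2 and 3 (adjusted p = 0.0944, 0.0835 and 0.0726; 0.0138 to 0.287 over its alternatives). The median, the mean and the direction of the test did not share a sign for the dopamine, immediate early, cAMP-PKA, p53, granulocyte and monocyte, niche, B and plasma cell, and neighbour lists. The neutrophil list lay at a median of 0.20, -1.40 and -0.70 against the WT mean in the libraries labelled KO replicates 1, 2 and 3.

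Genes beside the targeted loci were tested apart, since mice made from cells of another strain can keep DNA of that strain there. Of 191 tested genes within 10 Mb of Drd2 or Drd3, 21 (11%) were past the test, 15 of 120 near Drd2 and 6 of 71 near Drd3. Elsewhere 1209 of 11047 (10.9%) were, an odds ratio of 1.01 (one-sided Fisher's exact test, p = 0.526). Btla (chromosome 16, 45224315 to 45257670) was among the 6.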

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

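The term for Y-linked transcripts and the comparison without the 2 KO libraries lacking them were chosen after the data were seen. Both take the difference between the groups from KO replicate 2 alone. All 1240 genes kept their direction in each alternative that tested them. They were selected in these same libraries, and several settings change the test but not the fold, so this is no independent check. Between 1120 and 1309 genes were called with other pseudocounts, scalings, robust eBayes or a mean of at least 5 FPKM, 918 with no trend, 1574 with voom (43.1% of them higher) and 1628 with array weights. With no filter on low values, which adds 8002 genes, 588 were called (335 higher, 253 lower). Other thresholds gave 2049 at an adjusted p under 0.1 (1027 and 1022), 326 at a log2 fold change of at least 1 (196 and 130) and 3727 without overlap of the groups (1839 and 1888). The term for Y-linked transcripts gave 373 (214 and 159), and 514 (265 and 249) were called without the 2 KO libraries lacking them, where the lone KO library is assumed to vary like the WT libraries. With 1 library left out the count ran from 370 (212 and 158) to 1598 (764 and 834), all with 5 samples; why the count depends on the library left out was not tested. With the replicate block, 805 were called (436 and 369), 768 of them among the 1240. Deviations of libraries with the same number correlated at -0.031, 0.045 and -0.116, and not every library correlated best with its own number. No pairing by number was seen, but so few libraries per group cannot exclude one. Of 102 named genes, 39 missed the threshold with the term for Y-linked transcripts, 24 with no filter and at most 32 with 1 library left out. The replicate block also brought calls of the interferon and neutrophil lists (adjusted p = 0.0487 and 0.0439). Camera called 7 to 11 lists over the settings with a preset correlation of 0.01, and 0 with an estimated one (3 at an unadjusted p under 0.05). For the 8 lists called in the main comparison the estimated correlation was higher, from 0.0510 (lymphoid priming) to 0.601 (erythroid cells). A higher correlation widens the spread that camera allows for a list. Why the count varied over the settings with a preset correlation was not tested. The share of genes called within 10 Mb of Drd2 or Drd3 stood on the other side of the share elsewhere with no filter (2.66%), a mean of at least 5 FPKM (14.4%), a common sum (9.42%), quantile normalization (11%), no trend (6.81%), robust eBayes (11%), array weights (13.6%), the replicate block (5.76%) and libraries with Y-linked transcripts (4.19%), and was 4.19 to 15.2% with 1 library left out, all with Fisher's exact p of at least 0.282; the cause was not tested. A value of 0 means less than about 0.0693 to 0.0921 FPKM for a transcript of 2000 bases.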

Other observations

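The added lists and the tests in this part were all chosen after the results they address were seen. The p-values of the added lists are therefore no independent support. Genes of haem synthesis rose in the libraries labelled KO: 4 of 9 passed (6 adjusted over the list alone) and none fell, with a median log2 fold change of 0.70 (limma's camera adjusted p = 0.00260, fry adjusted p = 0.0349; adjusted p = 0.270 with an estimated correlation). They included Alad, from 72.7 ± 3.65 to 186 ± 19.6 FPKM (SD, n = 3), Fech and Cpox. Cpox missed the threshold without WT replicates 1, 2 and 3 and KO replicates 2 and 3 (adjusted p = 0.0712, 0.108, 0.0898, 0.0606 and 0.0512; 0.00904 to 0.108 over its alternatives). Imprinted genes rose as well, 4 of 9 (6 adjusted over the list alone) with none falling and a median of 0.62 (camera adjusted p = 0.000534, fry adjusted p = 0.00534; adjusted p = 0.0891 with an estimated correlation): Ndn, from 9.01 ± 1.66 to 30.4 ± 8.42 FPKM, Cdkn1c, Snrpn and Sgce. Snrpn missed the threshold without WT replicate 2 (adjusted p = 0.0631; 0.00911 to 0.0680 over its alternatives) and Sgce without WT replicates 1, 2 and 3 and KO replicate 1 (adjusted p = 0.0637, 0.0631, 0.0779 and 0.0578; 0.00975 to 0.109 over its alternatives). Ndn and Cdkn1c are also in the stem cell list.

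Mast cell proteases had 2 of 5 rising, Cma1 and Tpsb2 (3 adjusted over the list alone), and a median of 1.55. Limma's camera gave an adjusted p of 0.0108 (0.210 with an estimated correlation) and fry 0.0918, for a list chosen after these 2 genes were seen. The median was that of Gzmb, which did not pass (limma adjusted p = 0.0503). Cpa3 (0.11) and Mcpt8 (-0.33) did not pass either. The mast cell and basophil list fixed before was not called (camera adjusted p = 0.107). In the amino acid response list 2 of 20 rose and 1 fell (2 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.579). The pseudokinase gene Trib3 rose from 5.58 ± 0.670 to 18.0 ± 1.73 FPKM and the asparagine synthetase gene Asns from 15.5 ± 1.12 to 43.7 ± 8.37 FPKM, while the transporter gene Slc7a5 fell by 0.50 on the log2 scale. Slc7a5 missed the threshold without WT replicates 1, 2 and 3 (adjusted p = 0.0607, 0.102 and 0.0657; 0.0124 to 0.153 over its alternatives). In 13 called genes every library of one group was below 0.5 FPKM and every library of the other at 2 FPKM or more, 11 higher and 2 lower in the libraries labelled KO. The short RNA genes Mir451 (higher; 2, 2 and 1 recovered reads in the libraries labelled KO) and Gm23475 (lower; 1, 2 and 1 in those labelled WT) rest on few reads, and with limma's voom neither passed (adjusted p = 0.102 and 0.131; 0.000349 to 0.102 and 0.00153 to 0.131 over their alternatives). The pseudogene Gm15459 was at most 0.0770 FPKM in those labelled WT and 73.1, 71.6 and 82.1 FPKM in those labelled KO. Of the 13, 12 lay on other chromosomes than Drd2 and Drd3. The remaining gene, Btla (lower), starts at 45224315 on chromosome 16, within 10 Mb of Drd3, which ends at 43822932. Within 2 Mb of these 13, 45 of 494 tested genes were called (9.11%, against a median of 10.7% in 10000 random draws; permutation p = 0.847).

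The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Limma called 1240 genes in the real split (623 higher, 617 lower; 3128 at an unadjusted p under 0.05) and 0 in each of the other 9 (165 to 703 at an unadjusted p under 0.05), so 1 of the 10 splits gave as many in all 3 counts. Camera called 8 lists in the real split and up to 12 in the others, and 5 of the 10 splits, the real one included, reached 8 or more. Fry called 7 lists in the real split and 0 in each of the others, so 1 split gave as many. Each of the other 9 splits mixes both groups on either side, so a difference between the groups widens the spread there. Low counts in these splits are therefore no support for the real one.

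Drd3 had reads in each library labelled KO and in none labelled WT. An exchange of 1 library of each group would put a library out of place in both, and 0 libraries were out of place. An exchange of the labels of all 3 libraries of each group stays open, since Drd2, which might have decided it, summed to 0 FPKM over the 6 libraries. Transcription from an altered Drd3 locus may also leave reads, and the 72 reads have no position within the gene in this table. The exchange of all labels and the altered locus cannot be told apart here, and the former would turn every direction given.

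In the libraries labelled KO, 19 of 31 stem cell genes rose and 8 of 16 progenitor, 32 of 52 G2 and M phase and 15 of 43 S phase genes fell, though none of these lists passed limma's camera with an estimated correlation (adjusted p = 0.329 with an estimated correlation for each). Unequal sex of the libraries may contribute. With a term for Y-linked transcripts the median was 0.68 against 0.83 without it for the stem cell list and -0.71 against -0.68 for progenitors. It was -0.42 against -0.60 for G2 and M phase and -0.27 against -0.44 for S phase. These medians kept their sign, but they rest on KO replicate 2, the 1 KO library with Y-linked transcripts. A single library cannot show the spread between KO animals, so how much sex contributes stays open. A larger share of stem cells within the sorted gate may contribute as well. Of the 31 members, 11 had a 95% interval wholly below the median of the list, Hlf, Hoxa9 and Meis1 among them. This count cannot decide it, since the yardstick is the median of these same members. Nor need they rise alike, as markers already high in all cells of the gate would stay behind. A larger share of stem cells therefore stays open. An effect of the genotype within each cell was not tested, since sorted cells were measured in bulk.

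Immunoglobulin transcripts were high in the libraries labelled KO replicates 1 and 3, the 2 that lack Y-linked transcripts, and made up 0.226 and 0.126% of their reads, against 0.0178 to 0.0477% in the other 4. RNA of few plasma cells, which the lineage gate is meant to remove, may be a source: 1 kappa variable segment held 99.6% (Igkv6-20) and 91.5% (Igkv12-46) of the kappa variable reads, and Igj was at 39.8 and 33.8 FPKM against at most 0.530 in the others. Other plasma cell genes did not all go with this: in KO replicates 1 and 3, Mzb1 was at 1.23 and 7.53 FPKM (0.377 to 3.04 in the others), Xbp1 at 85.6 and 119 (64.2 to 88.2), Sdc1 at 12.8 and 10.9 (9.42 to 16.5), Derl3 at 1.76 and 1.10 (0.719 to 1.66), Tnfrsf17 at 0.340 and 0 (0 to 0.209) and Prdm1 at 0.808 and 0.201 (0.117 to 0.404), while Fkbp11, Sec11c and Ssr4 in neither library lay above all of the others, which keeps this source open. Reads carried over from 1 of the 2 libraries to the other are argued against, as each leading segment had 0 reads in the other library. An effect of the genotype stays open: Igkc stood below 100 times the highest WT value in 1 library labelled KO, replicate 2, but an effect need not appear in every library.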
